A study of Mus musculus with 12 samples.

How the data were processed

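The deposited table holds 1 column for each of 12 libraries and 27179 genes named by Entrez ID. Per the labels' protocols, RNA was isolated from pelleted cells with a DNase step, selected for poly(A), made into libraries with the NEBNext Ultra II RNA kit and sequenced on an Illumina NovaSeq instrument. Per the submitters' processing notes, fastp 0.23.2, HISAT2 2.2.1, featureCounts 2.0.1 and DESeq2 2.11.40.7 were used with the builds mm10 and GRCm38; their order and options are not given in the sources used here. Per the file headers, the values come from featureCounts counts, and the deposited table is called normalized by its name, with no method given. The deposited values behave as a signal in which each count was divided by a library size factor, as every value in a column was a whole multiple of 1 step (100% of values within a tolerance of 0.01 reads), so the whole reads were recovered by division. The values are not corrected for gene length, and whether counting used strand is not given in the sources used here. Of the IDs, 25275 were named from the RefSeq GRCm38.p6 gene table and 18 from GENCODE, and 1886 have no name. Coordinates are from the RefSeq table, in the build the labels name.

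Libraries were grouped by their titles. One control column has line and replicate numbers that match no title, and its place in the control group rests on the control name; it could be read as another control line. It was used as a control library with no replicate number. Libraries held 28902562 to 38077987 recovered reads. Replicates of a group differed by more than counting noise (chi-square per degree of freedom 4.30 to 16.1, reads per gene), so no pair was treated as 1 library deposited again. This does not show that they came from separate cultures.

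Genes with a value of at least 10 in at least 3 libraries were kept (13939). Values were transformed as log2(value + 1) and fitted with limma 3.58.1 (trend, all 12 libraries in 1 fit, two-sided) in R 4.3.3, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons numbered 5. A further one, ciliobrevin D-treated Actr3 KO against control, was added after the data were seen. The 22 fixed gene lists were tested in the first 3 comparisons with camera (preset correlation 0.01, Benjamini-Hochberg over 66 list and comparison pairs) and again with an estimated correlation; with the estimate no pair was called. Lists covered Arp2/3 subunits and their regulators, formins, SRF and MRTF, YAP and TAZ, NF-kB, interferon, intraflagellar transport, motile cilia, Hedgehog, dynein, collecting duct, epithelial adhesion, mesenchymal and matrix, cell cycle, p53, cholesterol, aryl hydrocarbon receptor, ATF4, hypoxia and glycolysis, immediate early genes and markers of other cell types. A further 3 lists (heat shock genes, NRF2 targets, stratified epithelium and urothelium genes) were added after the data were seen and are reported only in the closing section.

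Named genes were chosen by a rule set before the data were examined: Actr3 and Ift88; per comparison the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 100 in the higher group and no overlap between the groups (chance separates 10% of genes with 3 against 3 libraries), without predicted or clone-named models; and up to 4 called members per list with the smallest adjusted p, or 2 with the smallest p if none was called. The groups, the 5 comparisons and their tests, the 22 fixed lists and all alternatives but the last one below were also set before the data were examined; the additions named above and some tests of the closing section, named there, were not. Where a group held 0 reads of a gene, the fold is a bound against 3 reads over the group. With 1 to 3 reads, a ratio with an exact conditional 95% interval is given. Alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, quantile normalization, TMM rescaling, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, fits of only the 2 groups compared, the replicate number as a block, a threshold of at least 2-fold, and leaving out each library. Removing chromosome medians was added after the data were seen.

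The steps were tested on simulated data: negative binomial counts for the 13939 genes, with 200 genes changed in the Actr3 KO group, 50 at each fold. The 200 were drawn from genes with a mean of at least 50, so recovery of lower genes was not tested. For limma, counts were scaled by the size factors used to draw them. In the data, 9724 genes were called in Actr3 KO against control. Scaling and the share of false calls were not tested with that many changes. In Actr3 KO against control, limma recovered 68% of genes changed 1.25-fold, 94% at 1.5-fold, 98% at 2-fold and 100% at 4-fold. In dKO against Actr3 KO these shares were 58%, 98%, 100% and 100%, and for ciliobrevin D 58%, 100%, 100% and 100%. Over 20 draws, false calls were on average 5.02% of calls in Actr3 KO against control, 4.14% in dKO against Actr3 KO and 5.97% for ciliobrevin D, with a highest value of 8.54% for ciliobrevin D; in the separate draw used for recovery they were 5.76%, 6.32% and 10.1%. In each comparison both changed lists and none of 20 unchanged lists were called by camera. Genes were drawn independently of each other, so the draw does not test camera on correlated genes. In the data the estimated correlation reached 0.487, for cholesterol synthesis genes. Of the 200 changed genes, 172 were found as moved back in dKO and 174 with ciliobrevin D.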

Results

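Polyadenylated RNA was sequenced from 12 samples of mIMCD3 cells, a mouse line derived from the inner medullary collecting duct of the kidney. The cells had been grown to confluence for 48 h in medium with 10% fetal calf serum and then starved of serum for 24 h. There were 4 groups of 3 libraries: a control line, a line labelled as an Actr3 knockout (Actr3 KO), a line labelled as a knockout of both Actr3 and Ift88 (dKO), and the Actr3 KO line given 0.5 µM ciliobrevin D, an inhibitor of cytoplasmic dynein, in the starvation medium, where the protocol otherwise added solvent. Actr3 encodes ARP3, a core subunit of the Arp2/3 complex that nucleates branched actin filaments, and Ift88 encodes a component of the intraflagellar transport machinery that builds primary cilia. Recovered reads per library ranged from 37001577 to 38077987 in control, 31425219 to 34977447 in Actr3 KO, 30391369 to 32588460 in dKO and 28902562 to 32544817 with ciliobrevin D. The 10 genes with the most reads took 5.18% to 5.90% of reads in control, 8.69% to 10.2% in Actr3 KO, 5.98% to 6.16% in dKO and 9.05% to 10.1% with ciliobrevin D. Across genes, log2 values correlated at 0.993 to 0.996 within groups and at 0.942 to 0.974 between groups. Genes are not independent replicates, so these coefficients only describe similarity. Each genotype was 1 line, so a line and its genotype could not be separated. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. One control column carries a name that matches no control title exactly and could be read as another control line, and was used as a control library without a replicate number. Values are normalized counts (mean ± SD, n = 3), and fold changes are on the log2(value + 1) scale, which understates the change of low genes.

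The edited genes were examined first. Actr3 (Entrez 74117, chromosome 1, 125392905 to 125435727 in GRCm38) had 8336 ± 293 normalized counts in control, 1218 ± 111 in Actr3 KO, 871 ± 38.6 in dKO and 1573 ± 180 with ciliobrevin D. Its log2 fold change in Actr3 KO against control was -2.78 ± 0.07 (SE, limma adjusted p = 4.48e-17). Ift88 (Entrez 21821, chromosome 14, 57424064 to 57517936 in GRCm38) had 457 ± 14.9 in control, 617 ± 34.2 in Actr3 KO, 604 ± 29.8 in dKO and 438 ± 4.29 with ciliobrevin D. Its level in dKO differed from that in Actr3 KO by -0.03 ± 0.07 on the log2 scale (limma adjusted p = 0.725). After chromosome medians were removed, an alternative chosen after seeing the data, this became -0.18 (adjusted p = 0.0355, range over all alternatives 0.0355 to 0.947). Counts over a whole gene do not show whether a short edit disrupts the protein, so the Ift88 counts check nothing about the label.

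**Figure D1:**
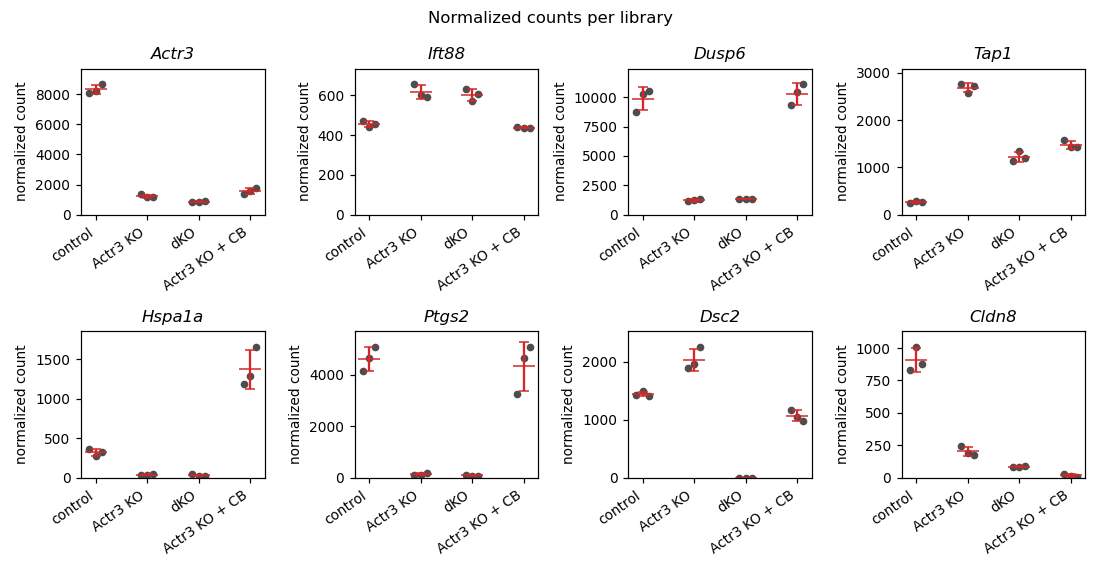
Normalized counts of 8 genes (y axes, linear, starting at 0) in the 4 groups (x axes). Grey points are the 3 libraries of a group, red bars are the mean ± SD, and CB is ciliobrevin D. Actr3 fell from 8336 in control to 1218 in Actr3 KO, Dsc2 was at 0 in the 3 dKO libraries, and Dusp6 was at 1221 in Actr3 KO and 1344 in dKO.

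The first comparison asked what differed between the Actr3 KO and control lines. Interferon-stimulated genes were higher in Actr3 KO and growth factor and immediate early genes were lower. Of 39 interferon-stimulated genes, 34 rose and 1 fell, with a median log2 fold change of 1.40 (limma camera adjusted p = 2.5e-13, and adjusted p = 0.332 with an estimated correlation); 35 were called when adjusted over the list alone. Tap1, a peptide transporter of antigen presentation, rose from 267 ± 16.6 to 2684 ± 93.8, the immunoproteasome subunit Psmb9 from 40.2 ± 7.73 to 413 ± 25.4, and Parp14 from 466 ± 59.1 to 2284 ± 132. Of 29 interleukin, growth factor and immediate early genes, 28 fell and none rose (median -1.73, camera adjusted p = 3.34e-13, and adjusted p = 0.332 with an estimated correlation); 29 were called when adjusted over the list alone. The ERK phosphatase Dusp6 fell from 9859 ± 985 to 1221 ± 102, Dusp4 from 2961 ± 278 to 492 ± 30.7 and Ier3 from 10872 ± 1364 to 1556 ± 112.

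Genes of metabolism and of the Arp2/3 complex also moved in groups. Of 29 hypoxia and glycolysis genes, 24 fell and 1 rose (median -0.99, camera adjusted p = 2.74e-08, and adjusted p = 0.332 with an estimated correlation), with 25 called when adjusted over the list alone. Hexokinase 2 (Hk2) fell from 6775 ± 571 to 1002 ± 96.8 and lactate dehydrogenase A (Ldha) had a log2 fold change of -1.70 ± 0.08 (SE). Of 24 cholesterol synthesis genes, 22 fell and none rose (median -0.55, camera adjusted p = 9.04e-06, and adjusted p = 0.426 with an estimated correlation), with 22 called over the list alone; Cyp51 fell by 1.23 and Idi1 by 1.45 on the log2 scale. All 9 tested Arp2/3 subunits fell, also when adjusted over the list alone (median -0.63, camera adjusted p = 2.14e-05, and adjusted p = 0.332 with an estimated correlation), among them Arpc3, from 5495 ± 253 to 2691 ± 248, and Actr2, from 9522 ± 250 to 5802 ± 60.4. The 9 include Actr3, the edited gene itself (log2 fold change -2.78), and the list was not tested without it. Of 25 p53 targets and cell cycle inhibitors, 17 fell and 4 rose (camera adjusted p = 0.00569, and adjusted p = 0.426 with an estimated correlation), with 22 called over the list alone. Of 31 ATF4 and unfolded protein response genes, 18 fell and 6 rose (camera adjusted p = 0.014, and adjusted p = 0.55 with an estimated correlation), with 24 called over the list alone; this list call was also lost after quantile normalization (adjusted p = 0.0581, range over the alternatives with the preset correlation 0.00303 to 0.0581).

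The other fixed lists were not called by camera in this comparison, although single members passed the gene test. Over all tested genes 69.8% were called, so a high count of called members does not by itself set a list apart. Among SRF and MRTF targets, which include actin and its binding proteins, 13 of 24 fell and 5 rose (camera adjusted p = 0.166), and beta-actin (Actb) fell by 1.31 on the log2 scale. Among 31 NF-kB and inflammatory genes, 16 rose and 9 fell (adjusted p = 0.231). Their median was 0.29 and their mean -0.15, so the signs differed. Ptgs2, the inducible cyclooxygenase, fell from 4622 ± 467 to 129 ± 29.9, and complement C3 rose from 149 ± 16.7 to 2152 ± 246. Of 28 collecting duct and cystic kidney genes, 14 fell and 7 rose (adjusted p = 0.37), with lower Krt19 (log2 fold change -1.77) and Aqp1 (-1.77) and higher Pkd1 (1.44). Of 30 epithelial adhesion and tight junction genes, 14 fell and 6 rose (adjusted p = 0.149). Of 36 intraflagellar transport and BBSome genes, 16 rose and 10 fell (adjusted p = 0.6), and of 38 cell cycle genes, 18 fell and 5 rose (adjusted p = 0.0632). The cell cycle list passed the threshold without the filter on low values (adjusted p = 0.0217), without control replicate 3 (adjusted p = 0.0300) and after chromosome medians were removed (adjusted p = 0.0486), with a range over the alternatives of 0.0217 to 0.473. Among 9 tested markers of other cell types, 4 rose and 1 fell (adjusted p = 0.787); one of them, Pdgfra, had a log2 fold change of 1.89, which was 1.15 without control replicate 3. Adjusted over the list alone, each of these lists had as many called genes. Median, mean and test also differed in sign for formins and linear actin nucleators (median 0.00, mean 0.03, higher in the test), motile cilia genes (median -0.06, mean -0.02, higher in the test) and markers of other cell types (median 0.00, mean -0.06, higher in the test), none of them called.

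Single genes with the lowest fold changes included several that were nearly undetected in Actr3 KO. Zfp518b (Entrez 100515, chromosome 5) had 359 reads in control and 0 in Actr3 KO, which is at least 106-fold lower against a floor of 3 reads over the group. Ak4 had 461 reads in control and 1 in Actr3 KO, a ratio of 411 (95% exact counting interval 73.4 to 16261). Such intervals and floors cover counting error only. The gap junction gene Gja1 fell from 225 ± 25.2 to 1.66 ± 1.15, the chloride channel gene Cftr from 328 ± 31.6 to 3.72 ± 3.06, and Tbx15 from 262 ± 29 to 1.34 ± 0.633. The highest included the WNT antagonist gene Dkk2, which rose from 10.0 ± 3.36 to 626 ± 104, Nlrc5, a regulator of class I antigen presentation genes, from 6.48 ± 1.74 to 303 ± 21.4, and Oas3, from 10.6 ± 3.33 to 169 ± 24.6. H2-Q6, Apol9a and Apol9b were also among the highest, but each has close paralogs, so their counts are uncertain. In total 9724 of 13939 tested genes differed (limma, Benjamini-Hochberg adjusted), 4792 higher and 4932 lower; 1691 also differed at least 2-fold, 846 higher and 845 lower. The median log2 fold change of genes on chromosome 6 was -0.42 and that on chromosome 5 was -0.24.

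The second comparison asked what differed between dKO and Actr3 KO. Matrix, mesenchymal and YAP and TAZ target genes were lower in dKO, and Arp2/3 subunits were higher. Of 29 mesenchymal, matrix and TGF-beta response genes, 20 fell and 3 rose (median -0.88, camera adjusted p = 5.67e-06, and adjusted p = 0.332 with an estimated correlation), with 23 called when adjusted over the list alone. Tenascin C (Tnc) fell from 6618 ± 771 to 685 ± 29.1, the basement membrane collagen Col4a1 from 17449 ± 1810 to 2666 ± 93.8, and thrombospondin 1 (Thbs1) by 2.39 on the log2 scale. Of 23 YAP and TAZ targets, 18 fell and 1 rose (median -0.49, camera adjusted p = 4.67e-05, and adjusted p = 0.332 with an estimated correlation), with 19 called over the list alone; Ccn1 fell by 1.76 and Tgfb2 fell by 3.04 on the log2 scale. Of 24 SRF and MRTF targets, 14 fell and 3 rose (camera adjusted p = 0.0252, and adjusted p = 0.332 with an estimated correlation), with 17 called over the list alone. That call was lost with the stricter filter (adjusted p = 0.148) and after quantile normalization (adjusted p = 0.0617), with a range over the alternatives of 0.0129 to 0.148. Vinculin (Vcl) fell by 1.19 and filamin A (Flna) by 1.23 on the log2 scale.

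Of the 9 Arp2/3 subunits, 8 rose and 1, Actr3, fell (median 0.72, camera adjusted p = 0.000464, and adjusted p = 0.332 with an estimated correlation); 9 were called over the list alone. Arpc3 rose from 2691 ± 248 to 6369 ± 300 and Actr2 from 5802 ± 60.4 to 10849 ± 538. Of 24 Arp2/3 activators and regulators, 13 rose and 3 fell (camera adjusted p = 0.0341, and adjusted p = 0.332 with an estimated correlation), with 16 called over the list alone. That list call was lost without Actr3 KO replicate 1 (adjusted p = 0.0533) and after chromosome medians were removed (adjusted p = 0.122), with a range over the alternatives of 0.0199 to 0.122. In Actr3 KO against control this list had 10 lower and 6 higher members and was not called (adjusted p = 0.586).

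Lists tied to cilia were not called between dKO and Actr3 KO. Of 36 intraflagellar transport and BBSome genes, 12 rose and 8 fell (camera adjusted p = 0.891); Arl13b, a small GTPase of the ciliary membrane, fell by 0.88 and Ift22 had a log2 fold change of 0.94. Ift81 had a log2 fold change of 0.48, and its call was lost after chromosome medians were removed (0.06, adjusted p = 0.395, range over the alternatives 4.83e-12 to 0.395). Of 14 motile cilia genes, 4 fell and 2 rose (adjusted p = 0.816). Of 8 Hedgehog targets, 5 fell and 2 rose (adjusted p = 0.149, median -0.37 also with Gli2 at its bound). Gli2, a transcription factor of that pathway, had 246 reads in Actr3 KO and 0 in dKO, at least 86.1-fold lower. Of 29 tested members of the dynein and dynactin list, 17 rose and 7 fell (camera adjusted p = 0.129). Of 15 formins and linear actin nucleators, 10 fell and 3 rose (camera adjusted p = 0.12). The dynein list passed the threshold after chromosome medians were removed (adjusted p = 0.0486, range 0.0486 to 0.201). Interferon-stimulated genes showed no net shift, with 13 higher and 11 lower (adjusted p = 0.816). Tap1 fell by 1.13 and Cxcl10 had a log2 fold change of 1.29. Growth factor and immediate early genes had 15 lower and 4 higher members (adjusted p = 0.0894); this list passed the threshold without dKO replicate 2 (adjusted p = 0.0450) and after chromosome medians were removed (adjusted p = 0.0219), with a range of 0.0219 to 0.149. Cell cycle genes had 18 higher and 9 lower of 38 (adjusted p = 0.108) and passed the threshold with no filter on low values (adjusted p = 0.0484) and after chromosome medians were removed (adjusted p = 0.0174), with a range of 0.0174 to 0.178. Adjusted over the list alone, 18 intraflagellar transport and BBSome genes and 28 cell cycle genes were called, and the other lists here had as many as over all genes. Median and mean differed in sign for the lists of NF-kB (0.14 and -0.27), p53 (0.17 and -0.09), hypoxia (0.23 and 0.00), epithelial adhesion (-0.04 and 0.00) and intraflagellar transport genes (-0.03 and 0.00), and the test of other cell type markers was lower with a median of 0.05 and a mean of 0.16. None of these lists was called.

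Several of the lowest single genes were close to absent from dKO. Desmocollin 2 (Dsc2, Entrez 13506, chromosome 18, 20030633 to 20059554 in GRCm38), a desmosomal cadherin, had 6149 reads in Actr3 KO and 0 in dKO, at least 2152-fold lower. Bhlhb9 (chromosome X) had 2488 reads against 0, at least 873-fold lower, and Igfbp2 had 494 against 0, at least 173-fold lower. Galnt14 had 1159 reads against 2, a ratio of 610 (95% exact counting interval 168 to 5043), and Itga9 had 718 against 1, a ratio of 756 (interval 135 to 29895). Dkk3 fell from 2313 ± 181 to 25.2 ± 3.17 and the metalloproteinase inhibitor Timp3 from 413 ± 6.67 to 6.33 ± 2.29. Among the highest, keratin 4 (Krt4) rose from 44.6 ± 6.29 to 777 ± 29.9, Psca from 6.69 ± 2.35 to 205 ± 26.9 and Cdk14 from 7.96 ± 0.313 to 247 ± 15.9. Among collecting duct genes, of which 11 of 28 rose and 10 fell (camera adjusted p = 0.827), the water channel gene Aqp1 rose from 751 ± 46.2 to 4950 ± 357. In total 9164 genes differed, 4537 higher and 4627 lower; 1325 differed at least 2-fold, 347 higher and 978 lower. Median log2 fold changes were 0.40 on chromosome 10, 0.39 on chromosome 5, -0.41 on chromosome 16, -0.39 on chromosome 3 and -0.21 on chromosome 1.

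**Figure D2:**
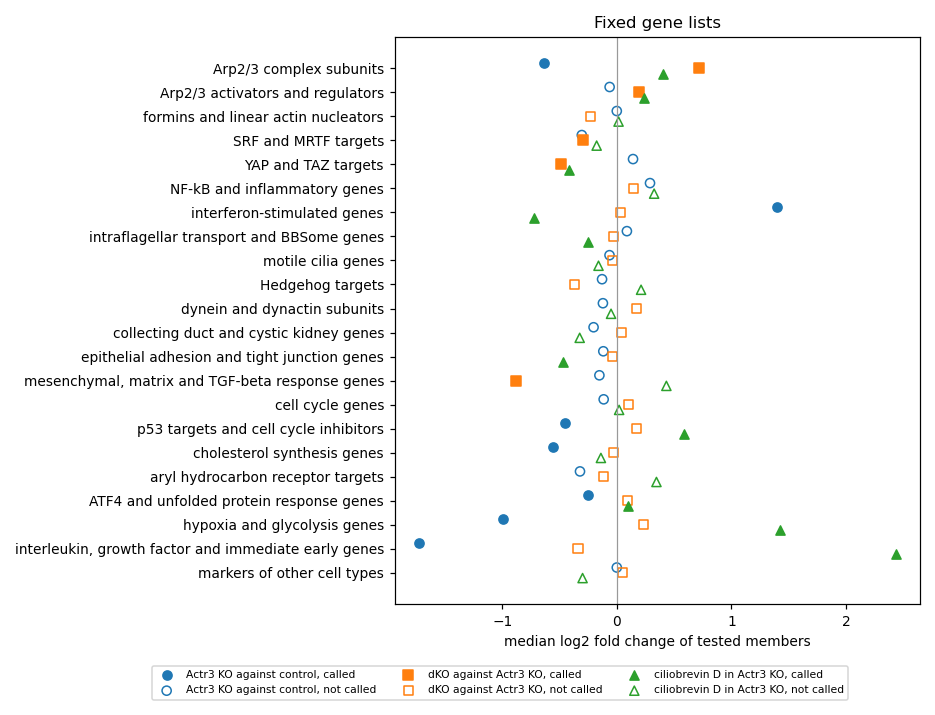
Median log2 fold change (x axis) of the tested members of the 22 fixed gene lists (y axis) in 3 comparisons. Filled symbols are lists called by camera with the preset correlation, and open symbols are lists that were not called. The immediate early list lies at -1.73 in Actr3 KO against control and at 2.44 with ciliobrevin D.

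The third comparison asked what ciliobrevin D changed in the Actr3 KO line. Growth factor, immediate early and glycolysis genes rose, while interferon-stimulated genes fell. Of 29 interleukin, growth factor and immediate early genes, 28 rose and none fell (median 2.44, camera adjusted p = 2.85e-18, and adjusted p = 0.332 with an estimated correlation), with 28 called when adjusted over the list alone. Dusp6 rose from 1221 ± 102 to 10276.5 ± 909, Dusp4 from 492 ± 30.7 to 5275 ± 628 and Klf4 from 296 ± 25.4 to 2629 ± 391. Of 29 hypoxia and glycolysis genes, 27 rose and none fell (median 1.42, camera adjusted p = 2.38e-15, and adjusted p = 0.332 with an estimated correlation), with 27 called over the list alone; Hk2 rose from 1002 ± 96.8 to 10212.5 ± 1333 and the prolyl hydroxylase Egln1 from 2069 ± 114 to 10486 ± 889. Of 25 p53 targets and cell cycle inhibitors, 18 rose and 4 fell (camera adjusted p = 8.63e-05, and adjusted p = 0.332 with an estimated correlation), with 22 called over the list alone. Of 31 ATF4 and unfolded protein response genes, 15 rose and 7 fell (camera adjusted p = 0.0216, and adjusted p = 0.55 with an estimated correlation), with 22 called over the list alone; that call was lost after quantile normalization (adjusted p = 0.0711, range over the alternatives 0.00956 to 0.0711). Its member Atf3 rose from 1360 ± 252 to 28252 ± 2989. Of 39 interferon-stimulated genes, 32 fell and 3 rose (median -0.72, camera adjusted p = 7.66e-06, and adjusted p = 0.332 with an estimated correlation), with 35 called over the list alone; Ifit3 and Ifit3b, close paralogs whose counts are uncertain, fell by 1.46 and 1.42, while Cxcl10 rose by 2.44 on the log2 scale.

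Genes of cilia and cell junctions were lower with ciliobrevin D. Of 36 intraflagellar transport and BBSome genes, 24 fell and 2 rose (median -0.25, camera adjusted p = 0.000762, and adjusted p = 0.426 with an estimated correlation), with 26 called over the list alone; Ift140 fell by 0.63 and Bbs1 by 0.67 on the log2 scale. The 14 motile cilia genes had 6 lower and 2 higher members and were not called (adjusted p = 0.285), but Foxj1, a regulator of motile cilia genes, fell from 2167 ± 47.8 to 678 ± 168. Of 30 epithelial adhesion and tight junction genes, 19 fell and 7 rose (camera adjusted p = 0.0188, and adjusted p = 0.426 with an estimated correlation), with 26 called over the list alone; E-cadherin (Cdh1) fell from 13980 ± 1415.5 to 6278 ± 431 and claudin 8 (Cldn8) from 202 ± 36.8 to 17.6 ± 12.5. Of 23 YAP and TAZ targets, 16 fell and 4 rose (camera adjusted p = 0.0077, and adjusted p = 0.426 with an estimated correlation), with 20 called over the list alone. Of the 9 Arp2/3 subunits, 8 rose and none fell (camera adjusted p = 0.00148, and adjusted p = 0.332 with an estimated correlation), with 8 called over the list alone. Of 24 Arp2/3 activators and regulators, 15 rose and 3 fell (camera adjusted p = 0.019, and adjusted p = 0.332 with an estimated correlation), with 18 called over the list alone; the call was lost after quantile normalization (adjusted p = 0.0858, range 0.0106 to 0.0858). Cholesterol synthesis genes had 11 lower and 3 higher of 24 and were not called (adjusted p = 0.166), but passed the threshold after quantile normalization (adjusted p = 0.0307, range 0.0307 to 0.296). Of 6 tested aryl hydrocarbon receptor targets, 3 rose and 2 fell (adjusted p = 0.415). The list of dynein and dynactin subunits, which form the target of the compound and its cofactor, also holds other genes, such as Pafah1b1, Nde1 and Hook1. Of its 29 tested members, 12 rose and 9 fell (camera adjusted p = 0.827). Adjusted over the list alone, 13 cholesterol synthesis genes were called, and the other uncalled lists named here had as many as over all genes. Median, mean and test differed in sign for markers of other cell types (median -0.30, mean 0.29, lower in the test, adjusted p = 0.891), SRF and MRTF targets (-0.18, -0.01, higher), dynein and dynactin subunits (-0.05, 0.04, higher) and formins and linear actin nucleators (0.01, 0.01, lower), none of them called.

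Single genes with the highest fold changes included Sprr1a, a cornified envelope gene, which rose from 20.9 ± 5.58 to 1214 ± 218, and the heme oxygenase gene Hmox1, from 719 ± 99.8 to 22200 ± 2751. Ptgs2 rose from 129 ± 29.9 to 4324 ± 941 and the chemokine gene Cxcl2 from 17.1 ± 8.07 to 621 ± 221. Hspa1a and Hspa1b, near-identical heat shock genes whose reads cannot be divided with certainty, rose by 5.28 and 4.10 on the log2 scale. Snord14d and Snord14e, which lie within introns of the heat shock cognate gene Hspa8, were also among the highest, and their counts are uncertain for that reason. The lowest included Dhrs3, a retinaldehyde reductase gene, which fell from 2021 ± 172 to 95.4 ± 57.0, and the collagen-binding integrin gene Itga2, from 456 ± 3.91 to 65.3 ± 27.0. In total 9136 genes differed, 4555 higher and 4581 lower; 1302 differed at least 2-fold, 817 higher and 485 lower. Treated control cells were not analysed here, so the response of this line could not be set against that of the control line. The median log2 fold change of genes on chromosome 5 was 0.22. In treated Actr3 KO against control, the comparison added later, 32 of 39 interferon-stimulated genes were still higher and 3 lower (median 1.16). Of 29 growth factor and immediate early genes, 19 were above control and 2 below (median 0.54). Of 29 hypoxia and glycolysis genes, 22 were above control and 4 below (median 0.56). These are counts of genes passing limma's adjusted threshold. Over all 13939 tested genes, 4604 were higher and 4467 lower in that comparison.

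The fourth comparison set dKO against control. Interferon-stimulated genes were higher in 38 of 39 cases and lower in 0, and growth factor and immediate early genes were lower in 29 of 29. Of hypoxia and glycolysis genes 21 of 29 were lower and 6 higher, of cholesterol synthesis genes 20 of 24 were lower and 1 higher, and of mesenchymal and matrix genes 18 of 29 were lower and 3 higher. Among SRF and MRTF targets 19 of 24 were lower and 1 higher, while Arp2/3 subunits were mixed, with 5 higher and 4 lower of 9. No list test was planned for this comparison, so these are counts of genes passing limma's adjusted threshold. Adjusted over the list alone, 21 SRF and MRTF targets were called, and the other lists named here had as many as over all genes. In total 9350 genes differed, 4463 higher and 4887 lower; 1736 differed at least 2-fold.

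The fifth comparison tested directly whether the ciliobrevin D-treated Actr3 KO and dKO differed. All 29 growth factor and immediate early genes were higher with ciliobrevin D than in dKO (median 2.49), as were 27 of 29 hypoxia and glycolysis genes, with 2 lower. Of mesenchymal and matrix genes 22 of 29 were higher and 3 lower (median 1.74). Interferon-stimulated genes were lower in 26 of 39 cases and higher in 7, and intraflagellar transport and BBSome genes were lower in 24 of 36 and higher in 3. Adjusted over the list alone, these lists had as many called genes. In total 10226 genes differed, 5161 higher and 5065 lower; 2165 differed at least 2-fold.

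Genes that differed between Actr3 KO and control often moved the opposite way in the other comparisons against Actr3 KO. Of the 9724 genes, 5415 (55.7%) moved back, wholly or in part, in dKO and 5835 (60.0%) with ciliobrevin D. Independent lists of these sizes would share 3196 and 3187 genes. Both comparisons use the same Actr3 KO values, which favours opposite signs even where the groups differ in unrelated ways. Independent lists are therefore not a valid baseline for genes moved back or further. With unchanged simulated groups that share the Actr3 KO libraries, the means were 0.04 and 0.07 genes in 100 draws; with no gene changed almost none is called, so these means do not measure what the shared libraries add to the counts. Further in the direction of the Actr3 KO change moved 1471 genes in dKO and 1094 with ciliobrevin D, where independent lists would share 3197 and 3187. At a threshold of at least 2-fold in both comparisons, 388 and 488 of 1691 genes moved back, where independent lists would share 80.4 and 79.0. At that threshold 125 genes moved further in dKO and 39 with ciliobrevin D, where independent lists would share 80.3 and 79.0. Of the 125, 97 were lower in both comparisons, against 59.3 for independent lists. Across genes, the Actr3 KO change correlated with the dKO change at r = -0.316 (simulated -0.514) and with the ciliobrevin D change at r = -0.510 (simulated -0.493). The correlation with the dKO change was weaker than in the simulated unchanged groups, and that with the ciliobrevin D change was close to theirs. The covariances were -0.193 and -0.279, against simulated values of -0.0123 and -0.0124. Among the 845 genes at least 2-fold lower in Actr3 KO, the median share of the change taken back was 0.50 with ciliobrevin D and 0.19 in dKO. Among the 846 that were higher, it was 0.37 and 0.41. These shares carry the same limit, since the genes were chosen by their Actr3 KO values. A move back need not be complete. Of the 9724 genes, 5605 (57.6%) were still called in the same direction in dKO against control. With at least 2-fold changes in both, these were 840 of 1691 (49.7%). Actr3 KO and dKO were here set against the same control libraries, which favours equal signs. Dusp6 was at 1344 ± 16.5 in dKO against 1221 ± 102 in Actr3 KO, a difference that did not pass the test (limma adjusted p = 0.094), whereas with ciliobrevin D it was at 10276.5 ± 909. The 2 responses correlated across genes at r = 0.198, with a covariance of 0.104. Simulated unchanged groups gave r = 0.487 and a covariance of 0.0123, because both responses use the same Actr3 KO libraries. With 3 such libraries no split into parts of at least 2 was possible. Part or all of the excess of genes moved back may therefore come from the shared Actr3 KO values, and a reversal was not established.

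**Figure D3:**
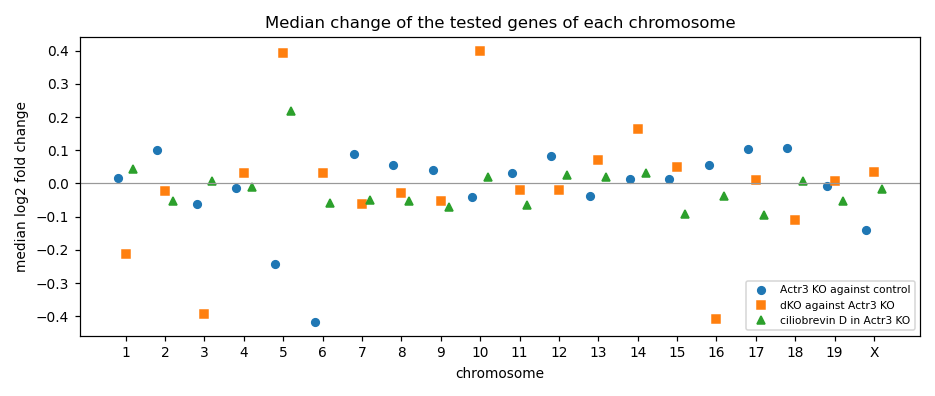
Median log2 fold change (y axis) of the tested genes of each chromosome (x axis) in 3 comparisons, 1 symbol per comparison. Chromosome 6 lies at -0.42 in Actr3 KO against control, and chromosomes 10 and 16 lie at 0.40 and -0.41 in dKO against Actr3 KO.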

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

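The removal of chromosome medians was chosen after seeing the data; the other alternatives were planned. Apart from the settings given next, the counts of changed genes ranged over the alternatives from 8766 to 9901 for Actr3 KO against control, 8403 to 9408 for dKO against Actr3 KO, 8384 to 9303 for ciliobrevin D, 8392 to 9631 for dKO against control and 9159 to 10638 for ciliobrevin D-treated Actr3 KO against dKO, with 4920 to 5587 genes moved back in dKO, 5323 to 5881 moved back by ciliobrevin D and 19 to 25 list tests called. Requiring at least 2-fold changes, which by construction leaves fewer genes, gave 1691 genes for Actr3 KO against control, 1325 for dKO against Actr3 KO, 1302 for ciliobrevin D, 1736 for dKO against control and 2165 for ciliobrevin D-treated Actr3 KO against dKO, with 388 moved back in dKO and 488 moved back by ciliobrevin D. The correlation across genes of the differences of dKO and of ciliobrevin D-treated cells from Actr3 KO was 0.237 with no filter on low values, against 0.198, with a jackknife SE of 0.0320; the lowest value over the alternatives was 0.181, and the cause was not tested. With an estimated correlation, 0 of the 66 list tests were called against 22 with the preset one. The estimates ranged from -0.020 for aryl hydrocarbon receptor targets to 0.487 for cholesterol synthesis genes, against the preset 0.01. That of growth factor and immediate early genes was 0.454. The 2 settings differ by more than the correlation. For aryl hydrocarbon receptor targets, with an estimate below the preset, the unadjusted camera p in Actr3 KO against control rose from 0.0808 to 0.111. For motile cilia genes, also below the preset, it went from 0.606 to 0.598. How far the estimates account for the lost calls was not tested. In Actr3 KO against control, edgeR on recovered reads called 9856 genes and DESeq2 9587. Without the unnumbered control library 9094 genes were called. No named gene or list reversed its direction among calls. Among 325 pairs of a named gene and a comparison, Ptprc in dKO against Actr3 KO lost its call with a pseudocount of 5 (adjusted p = 0.0516) and with DESeq2 (adjusted p = 0.0923, range over the alternatives 0.000617 to 0.0923), Lpcat2 without dKO replicate 1 (adjusted p = 0.0603, range 0.00498 to 0.0603) and Ift81 after chromosome medians were removed, and Ift88 gained one there.

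The replicate numbers did not pair the samples: the deviations of 15 same-numbered pairs correlated at -0.042 to 0.067. With the replicate block, which left out the unnumbered control library, 9080 genes were called in Actr3 KO against control, 9158 in dKO against Actr3 KO and 9118 with ciliobrevin D, and the cell cycle list gained a call in Actr3 KO against control (adjusted p = 0.0434). At this depth, genes near the floor of 3 reads have wide ratios, and folds of genes with 0 reads are bounds only.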

Other observations

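The lists of heat shock, NRF2 and stratified epithelium genes, the tests of clonal lines, of off-level Actr3 KO libraries, of a compound response apart from Actr3 and of chromosomes other than 5, and the removal of chromosome medians were chosen only after the results were seen. Heat shock genes were lower in Actr3 KO than in control in 24 of 24 cases (median log2 fold change -0.81, camera adjusted p = 3.36e-10, and adjusted p = 0.0777 with an estimated correlation). With ciliobrevin D, 22 of 24 rose (median 1.35, adjusted p = 0.0457 with an estimated correlation), and 18 were then above control and 3 below (median 0.50, camera adjusted p = 0.000119, and adjusted p = 0.272 with an estimated correlation). In dKO against Actr3 KO, 13 were higher and 5 lower, and the list was not called (median 0.24, camera adjusted p = 0.0619). These p-values were adjusted over 12 pairs of an added list and a comparison. Hspa1a, Hspa1b and Hmox1 were among the highest genes with ciliobrevin D in the results already seen. The heat shock and NRF2 lists are therefore not independent evidence of their direction. NRF2 targets, which defend against oxidants, were lower in Actr3 KO in 17 of 18 cases (adjusted p = 0.0457 with an estimated correlation), and 17 rose with ciliobrevin D (adjusted p = 0.0360 with an estimated correlation). Against control, 8 of 18 were higher with ciliobrevin D and 3 lower, and the list was not called (camera adjusted p = 0.0769, and adjusted p = 0.533 with an estimated correlation). In dKO against Actr3 KO, 11 of 18 were higher and 4 lower, and the list was not called (median 0.25, camera adjusted p = 0.0938). Hmox1 was at 8184 ± 1690 in control, 719 ± 99.8 in Actr3 KO, 536 ± 71.0 in dKO and 22200 ± 2751 with ciliobrevin D.

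Stratified epithelium and urothelium genes were lower in Actr3 KO than in control in 10 of 13 tested cases and higher in 1 (median -1.39, adjusted p = 0.0360 with an estimated correlation). In dKO against Actr3 KO 11 of 13 rose and none fell (median 1.81, camera adjusted p = 0.016 with an estimated correlation). With ciliobrevin D, 3 of 13 rose and 6 fell, and the list was not called (camera adjusted p = 0.963). Against control, 2 were then higher and 9 lower (median -1.15, camera adjusted p = 0.00303, and adjusted p = 0.0360 with an estimated correlation). The list was written after Krt4 and Upk3bl had been seen among the highest genes, so it is not independent evidence of its direction.

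In dKO, 130 genes were lower than in Actr3 KO by at least 3 on the log2 scale, 129 of them with a known position, over which the shares below were taken. Loss of a whole chromosome is argued against as the source of these losses. A share of 0.031 (95% exact interval 0.0085 to 0.0775) lay on a chromosome with a median of -0.4 or less. Only chromosome 16 passed that cut, at -0.408, with 4 of the genes. Whether chromosome 16 differed in copy number is a separate question, taken up below. Deletion of chromosome segments stays open, since a share of 0.202 (interval 0.136 to 0.281) had a nearest tested neighbour within 1 Mb lower by at least 1, against 0.131 for random genes. Such losses were seen between lines, with 94 genes in Actr3 KO against control, and only 2 were seen with ciliobrevin D within the Actr3 KO line. Rises of at least 3 numbered 50 in Actr3 KO against control, 23 in dKO against Actr3 KO and 87 with ciliobrevin D. Large changes as such were therefore not limited to comparisons between lines. A difference between clonal lines is a candidate explanation, but it cannot be told apart from an effect of Ift88, because each genotype is 1 line.

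Of the genes at least 2-fold lower in Actr3 KO, 339 were at least 2-fold higher with ciliobrevin D. The median share of this rise seen in dKO was 0.0795 (95% bootstrap interval 0.0274 to 0.123). In dKO itself, 29 of 29 growth factor and immediate early genes were lower than in control. The low share thus argues against off-level Actr3 KO libraries only if dKO left the 339 genes unchanged, which was not tested. After quantile normalization a share of 0.971 (exact interval 0.946 to 0.986) kept both signs and both calls at adjusted p under 0.05. The 2-fold limit that defined the set was not applied again, which favours a high share. The interval treats genes as independent and reaches below 0.95, so scaling between libraries stays open. With ciliobrevin D the set lay above control by a median of 0.276 (interval 0.164 to 0.381), with 142 genes above and 70 below. The rise may be a response to the compound apart from Actr3 or a reversal of the Actr3 KO change, and these cannot be told apart without treated control cells.

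Whole chromosomes differed between lines. In dKO against Actr3 KO, 78.5% of tested genes on chromosome 10 had a log2 fold change above 0, whether called or not. On chromosome 16 this share was 17.2%. The medians were 0.40 and -0.41, sizes near the 0.415 that a change between 3 and 4 copies would give. Chance placement of genes is argued against, since the largest median in 1000 shuffles was 0.108. A copy number difference between lines required that no chromosome shift within the Actr3 KO line. Chromosome 5 shifted by 0.219 with ciliobrevin D, past the bound of 0.2 set beforehand, so this prediction failed. The failure argues against copy number for chromosome 5 only if treated and untreated cells held equal copies, which was not measured. Against control, the chromosome 5 median was -0.243 in Actr3 KO, 0.155 in dKO and -0.019 with ciliobrevin D. Chromosome 6 lay at -0.418, -0.387 and -0.413 in these groups. Among the other 19 chromosomes, a set defined only after the chromosome 5 result, the largest shift with ciliobrevin D was 0.0937. Copy number may still account for those chromosomes, but no DNA was measured and this stays open.

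Splits of the 6 libraries of each comparison into 3 and 3 number 10, too few for a share under 0.05. In 1 of 10 splits, the real one, the count was as high as the real count, which in fits of only the 2 groups compared was 9870 genes for Actr3 KO against control, 9408 for dKO against Actr3 KO, 8720 for ciliobrevin D, 9631 for dKO against control and 9991 for ciliobrevin D-treated Actr3 KO against dKO. The highest count of any other split was 0 in each.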
